A study of Homo sapiens with 27 samples.

How the data were processed

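The series holds 27 RNA sequencing libraries of triple negative breast cancer cells in 9 groups of 3. Polyadenylated RNA was taken from pelleted cells kept in RNAlater, made into stranded mRNA libraries and sequenced on a NovaSeq instrument. Per the labels, the cells are MDA-MB-231, a line labelled MDAMB231_1GXLM that carries the MDA-MB-231 name (1GXLM from here on; the labels do not say how it was made), and SUM149PT. MDA-MB-231 has a control group and a group given AV535 at 500 ng. In 1GXLM there are a control group, a group given AV535 at 500 ng, a group labelled NOTCH3 shRNA and a group labelled PD-L1 shRNA. SUM149PT has a control group and groups given AV535 at 500 ng and at 1000 ng. AV535 was taken to be the antibody against NOTCH3 that the design text names without a code. The labels give its dose in ng with no volume and no time. The design text calls the controls untreated, whereas the protocol mentions a scrambled lentiviral control. The labels of the 3 control libraries of 1GXLM do not tell which of these they are, so a difference between an shRNA group and these controls includes transduction and selection if the controls are untreated.

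The values are raw gene counts, deposited as whole counts per gene and library, with no normalization, per the file headers. The submitters' processing notes name STAR 2.5.2b, Subread 1.5.1 and the GRCh38 (hg38) genome build. The annotation release, the strand setting and any filter on reads are not stated. The table lists 64253 genes by identifier and name; 56105 of the identifiers are in the name table used for symbols and positions, and 4146 of the genes lie on contigs other than the main chromosomes. No gene lacked a name, each of the 27 count columns matched 1 library by its title, and 0 pairs of libraries were identical. In 1GXLM the numbers of sequenced reads in the labels do not follow the count totals (counts came to 59.0% to 123% of the labelled reads over the 27 libraries), so groups were taken from the titles and treatments and the labelled read numbers were not used.

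Library totals ran from 69051435 to 137344891 counts. Protein coding genes took 95.2% to 97.1% of the counts, mitochondrial genes 3.02% to 6.89%, and the 20 most abundant genes of a library 7.79% to 11.3%. The limit set by a count of 0 was taken as 3 counts over the 3 libraries of a group together, which at these totals lies far below 1 CPM. These limits and the 95% counting intervals of ratios cover counting error only, since the reads carry no molecular identifiers.

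Genes were tested in R 4.3.3 with edgeR 4.0.16 (trimmed mean of M values factors, filterByExpr with its defaults, glmQLFit with robust settings, quasi-likelihood F test), separately for each line, on all libraries of that line. The MDA-MB-231 fit held 6 libraries and 20166 genes, the 1GXLM fit 12 libraries and 21450 genes, and the SUM149PT fit 9 libraries and 22600 genes. Their common biological coefficients of variation were 0.225, 0.077 and 0.0864. Comparisons between MDA-MB-231 and 1GXLM used a fit of 18 libraries and 22321 genes, and comparisons with SUM149PT a fit of all 27 libraries and 24855 genes. P values were adjusted by the Benjamini-Hochberg method over the genes of each comparison; an adjusted p under 0.05 was called, and a log2 change of at least 1 was counted as a larger change. Values per group are CPM on the scaled totals, given as mean and SD with n = 3. All tests are two-sided.

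The comparisons and their settings were fixed before the data were examined, as were 22 gene lists: NOTCH receptors, ligands and core components, NOTCH target genes, immune checkpoint ligands, type I interferon response, MHC class I antigen presentation, NF-kB and inflammatory cytokines, mesenchymal, epithelial and basal markers, stemness and plasticity markers, mitosis, DNA replication, hypoxia and glycolysis, unfolded protein and integrated stress response, cholesterol synthesis and uptake, YAP/TAZ targets, matrix proteases and inhibitors, lung metastasis-associated genes of MDA-MB-231, mitochondrially encoded mRNAs, and markers of leukocytes, endothelium and fibroblasts as other cell types. NOTCH3 is a member of both NOTCH lists. Lists were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison, and again with a correlation estimated from the data and with fry, which asks whether the members move on balance 1 way without comparing them with other genes. The genes named were set by a rule fixed at the same time: NOTCH3 and CD274 always; the 10 genes that rose most and the 10 that fell most among the called genes with a mean of at least 2 CPM in the higher group, all 3 libraries of 1 group above all 3 of the other and a symbol that is not a clone name; and up to 3 called members each way per list by lowest adjusted p. For comparisons of responses and doses the rule took 5 each way. Members of a list are also named, with their values, where they did not pass. Some genes that met the rule are left out of the text.

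The method was tested on simulated data built from these libraries, in which 50 genes were changed by a known fold. At a 2-fold change it recovered 8 of 50 genes in MDA-MB-231, 46 in the AV535 comparison of 1GXLM and 43 in the 1000 ng comparison of SUM149PT; at 1.25-fold it recovered 0, 16 and 18. Alternatives were DESeq2 1.42.0, limma-voom, relative log expression factors, no filter, a filter at 1 CPM in 3 libraries with a mean of 50 counts, a fit on the libraries of the contrast alone, a fit of all 27 libraries, thinning to the smallest total, factors without mitochondrial and top 20 genes, raw totals for the targeted genes, and leaving out each library. A fit of MDA-MB-231 without its 2 libraries that stood apart, and a fit with the ribosomal protein share as a covariate, were added after seeing the data. Overlaps between comparisons were set against n1 × n2/N per direction and against 5 simulations in which only the shared controls link the comparisons. Changes along chromosomes were summarised as medians over windows of 20 Mb holding at least 25 genes, against the 97.5th percentile of 1000 shuffles of the genes. Other splits of the libraries were counted: 10 for a pair of groups and 20 drawn for a difference of responses. Shares of RNA of another line and the levels of single SUM149PT libraries were computed as CPM on raw totals. Genes on the Y chromosome and XIST were left out of the named genes.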

Results

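Messenger RNA was sequenced in 27 libraries from 3 triple negative breast cancer lines, each group with 3 samples that the design text calls independent. MDA-MB-231 is a mesenchymal-like basal B line and SUM149PT an inflammatory breast cancer line with epithelial features. The third line, 1GXLM, carries the MDA-MB-231 name in its label. MDA-MB-231 came as control and AV535-treated cells (500 ng), 1GXLM as control, AV535-treated (500 ng), NOTCH3 shRNA and PD-L1 shRNA cells, and SUM149PT as control cells and cells given AV535 at 500 ng or 1000 ng. Library totals ran from 69051435 to 137344891 counts. Log2 changes are given for the first named group over the second with the standard error (SE) of the edgeR fit, and levels as CPM (counts divided by the scaled library total), mean ± SD with n = 3. All adjusted p values of single genes are edgeR quasi-likelihood values with the Benjamini-Hochberg correction.

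The series title and design text set the treatments against NOTCH3, a receptor of the Notch family, and PD-L1, the immune checkpoint ligand encoded by CD274, so both transcripts were examined first in every group. NOTCH3 (ENSG00000074181; GRCh38 chromosome 19, 15159038 to 15200981) was lowest in MDA-MB-231 controls at 0.87 ± 0.121 CPM. It stood at 7.39 ± 1.17 CPM in 1GXLM controls and, highest among the controls, in SUM149PT at 52.9 ± 1.4 CPM. CD274 (ENSG00000120217; chromosome 9, 5450503 to 5470566) was at 23.5 ± 3.79 CPM in MDA-MB-231 controls, 23.5 ± 1.87 CPM in 1GXLM controls and 2.3 ± 0.279 CPM in SUM149PT controls. In the libraries labelled NOTCH3 shRNA the NOTCH3 transcript was not lower than in controls: it stood at 7.77 ± 1.24 CPM, with a log2 change of 0.049 (SE 0.14, 95% interval -0.27 to 0.36, adjusted p = 0.829). The 3 libraries ranged from 6.35 to 8.53 CPM against 6.28 to 8.61 CPM in controls. CD274 fell slightly in them, to 19.1 ± 1.43 CPM, by 0.32 on the log2 scale (SE 0.069, adjusted p = 0.00119, all 3 libraries below all 3 controls). In the libraries labelled PD-L1 shRNA, CD274 fell to 12.6 ± 0.662 CPM, by 0.91 on the log2 scale (SE 0.070, adjusted p = 9.11e-09) or 1.88-fold, and NOTCH3 rose to 27.5 ± 3.06 CPM, a log2 change of 1.88 (SE 0.14, adjusted p = 2.55e-07) or 3.69-fold.

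Neither transcript was called after AV535 in any line. NOTCH3 changed by a log2 of 0.21 (SE 0.21) in MDA-MB-231 and by 0.011 in 1GXLM. In SUM149PT it changed by 0.11 (95% interval -0.004 to 0.219, adjusted p = 0.319) at 500 ng and by 0.12 (0.009 to 0.232, adjusted p = 0.484) at 1000 ng, where the interval lies above 0 at an unadjusted p of 0.0367. CD274 changed by -0.020, -0.11, -0.23 and -0.29 in the same order. The interval for NOTCH3 in 1GXLM was -0.304 to 0.327, so a change of 2-fold in either direction lay outside it.

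**Figure D1:**
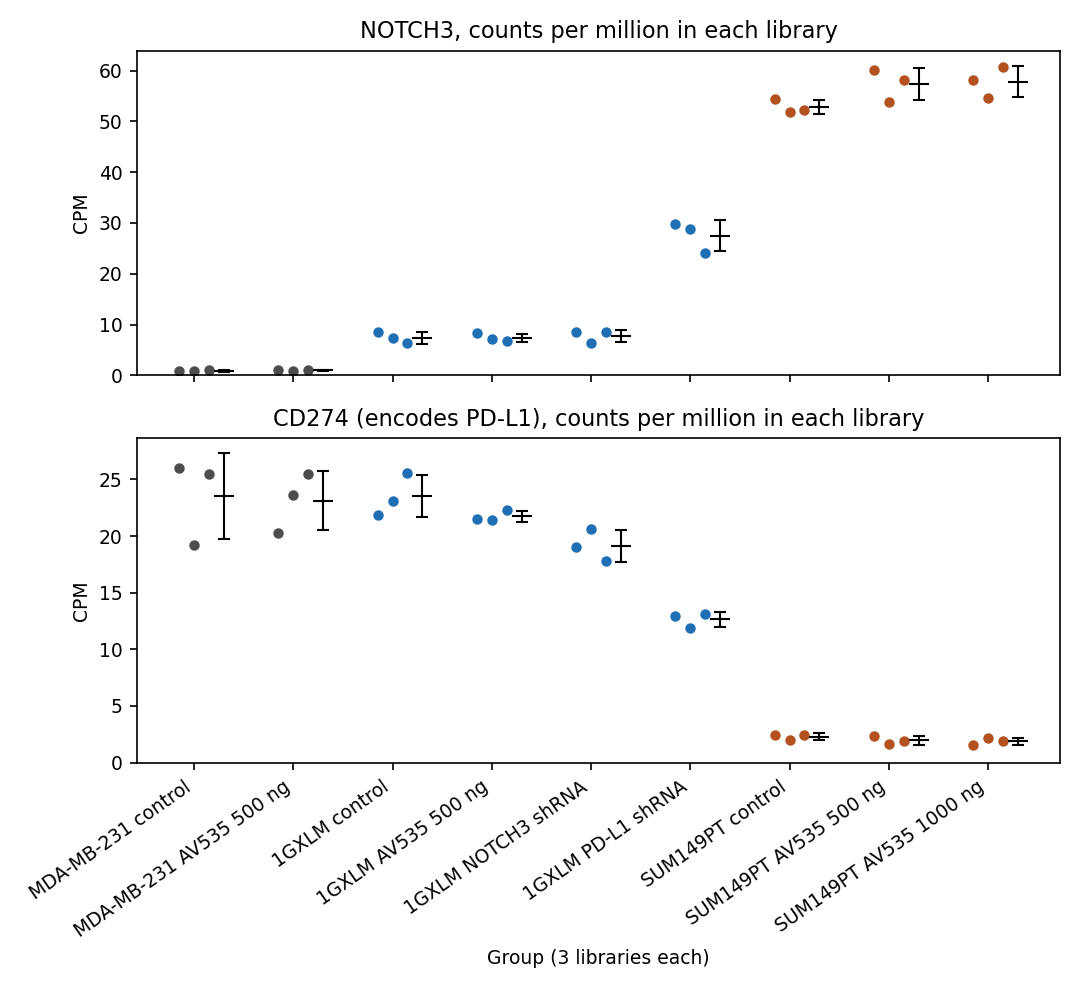
Level of NOTCH3 and CD274 (CPM, y axis) in each of the 27 libraries by group (x axis), with points for libraries and horizontal ticks and error bars for group means and SD. NOTCH3 in the NOTCH3 shRNA group (7.77 CPM) overlaps the 1GXLM controls (7.39 CPM), and the PD-L1 shRNA group has the lowest CD274 of the 1GXLM groups (12.6 CPM).

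Single genes of matrix degradation, adhesion, mucus and MHC class II were among the largest differences between the cells labelled NOTCH3 shRNA and 1GXLM controls. MMP1, the interstitial collagenase, rose from 38.7 ± 3.25 to 724 ± 70.2 CPM (log2 4.20, SE 0.075, adjusted p = 1.09e-17). The stromelysin MMP3 rose by a log2 of 2.64, while the protease inhibitor TIMP3 fell from 253 ± 1.09 to 8.59 ± 0.774 CPM. CDH11, a cadherin of mesenchymal cells, was at 217 ± 3.6 CPM in controls and had no count in the 3 libraries labelled NOTCH3 shRNA, at least 20400-fold lower when 3 counts over the group are taken as the limit. The gel-forming mucin MUC5B was at least 5730-fold lower and MUC5AC had 1 count (ratio 11900, 95% counting interval 2010 to 442000). AGR2, a protein disulfide isomerase needed for mucin folding, was at least 1070-fold lower. Reads of the 2 mucins can be shared between their near-identical repeats. HLA-DRA of MHC class II fell from 169 ± 3.95 to 0.041 ± 0.029 CPM and its chaperone CD74, the invariant chain, from 442 ± 42.9 to 0.859 ± 0.0113 CPM. Reads shared among HLA copies leave the exact HLA value uncertain.

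Among 21450 genes tested, 7947 were called, 3781 higher and 4166 lower in the libraries labelled NOTCH3 shRNA, and 1770 of them changed at least 2-fold (595 up, 1175 down). The genes that rose most also included NAP1L2 of the nucleosome assembly family (at least 377-fold) and ANO5 (at least 184-fold), the cancer-testis gene SSX1 (log2 7.09, SE 0.35), the O-glycosylation enzyme GALNT14 (6.27, SE 0.25), EPB41L3 (5.44), CD93 (4.88), the serotonin receptor HTR2C (4.62), CPEB1 (4.61) and KLHL13 (4.38). Those that fell most also included NLRP2 (at least 1220-fold), PTPRN2 (at least 983-fold), the adhesion molecule CADM1 (at least 408-fold) and HLA-DQB2 (at least 426-fold). GPRC5C had 1 count left, a ratio of 5350 with an interval of 907 to 2e+05.

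Epithelial markers fell as a group: of 28 measured, 22 fell, 0 rose and 6 did not pass (24 fell adjusted over the list alone), with keratin KRT19 from 74.3 to 0.851 CPM, the protease inhibitor SPINT1 by 4.20 and the transcription factor ELF3 by 3.21 on the log2 scale. For epithelial markers the adjusted p was 1.99e-13, and adjusted p = 0.005 with an estimated correlation. Hypoxia and glycolysis genes fell too, 19 of 30 against 1 that rose (21 and 1 adjusted over the list alone), with ALDOC down by 4.59, carbonic anhydrase CA9 by 2.10 and EGLN3 by 1.33, while VEGFA rose by 0.28. Camera gave hypoxia and glycolysis an adjusted p of 6.65e-07, and adjusted p = 0.0254 with an estimated correlation. Mesenchymal markers went both ways: 16 of 26 rose, among them ITGA5 (0.69) and SNAI2 (0.75), and 5 fell, among them S100A4 (from 211 to 5.48 CPM), FN1 (-0.77) and AXL (-0.45). The same numbers passed adjusted over the list alone, and camera called the list upwards (adjusted p = 0.00121; adjusted p = 0.267 with an estimated correlation). In cholesterol synthesis and uptake 13 of 25 fell and 1 rose (13 and 1 adjusted over the list alone), with FDFT1 (-0.71) below controls and SC5D (0.24) above. For cholesterol genes the adjusted p was 0.000606, and adjusted p = 0.267 with an estimated correlation. Of the unfolded protein and integrated stress response genes 15 of 29 rose and 4 fell (16 and 4 adjusted over the list alone), with the cystine transporter SLC7A11 (0.73), SESN2 (0.68) and the chaperone HSPA5 (0.37) up. Camera gave stress response genes an adjusted p of 0.0109, and adjusted p = 0.229 with an estimated correlation. Stemness and plasticity markers fell in 9 of 18 and rose in 3 (10 and 3 adjusted over the list alone), CD24 by 5.69, LGR5 by 3.38 and ID3 by 2.92, with CXCR4 (2.92) and ALDH1A3 (0.86) up. For stemness markers the adjusted p was 0.0202, and adjusted p = 0.267 with an estimated correlation.

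Further lists were called in the same comparison at p values nearer the threshold, and each lost the call with an estimated correlation. Type I interferon genes rose in 20 of 34 and fell in 10 (the same counts adjusted over the list alone): OAS1 (1.36), IFI44L (1.22) and MX1 (1.12) rose, BST2 (-4.42), IFI27 (-3.83) and XAF1 (-1.30) fell, and the median change was 0.29 while the mean was -0.068. Camera gave interferon genes an adjusted p of 0.0432, and adjusted p = 0.415 with an estimated correlation. That call ended without control replicate 1 (adjusted p = 0.0634) and without NOTCH3 shRNA replicate 1 (0.0839) or 2 (0.0595). MHC class I antigen presentation rose in 8 of 18 and fell in 2 (9 and 2 adjusted over the list alone), HLA-B by 0.81, HLA-F by 0.77 and the regulator NLRC5 by 0.74, with TAP2 at -0.25. For MHC class I the adjusted p was 0.0274, and adjusted p = 0.353 with an estimated correlation, and 0.0512 without control replicate 3. Mitosis genes fell in 9 of 30 and rose in 0, the same counts adjusted over the list alone, with ANLN (-0.50), KIF20A (-0.34) and CCNB2 (-0.29). Camera gave mitosis an adjusted p of 0.0238, and adjusted p = 0.539 with an estimated correlation, and 0.0512 without control replicate 3 and 0.127 without NOTCH3 shRNA replicate 3. YAP/TAZ targets fell in 13 of 24 and rose in 5 (13 and 6 adjusted over the list alone), with IGFBP3 (-2.25), TGFB2 (-1.70) and ANKRD1 (-1.16) down and ARHGEF17 (0.53) up. For YAP/TAZ targets the adjusted p was 0.0274, and adjusted p = 0.415 with an estimated correlation, and 0.0719 without NOTCH3 shRNA replicate 3. Fibroblast markers, taken as another cell type, rose in 5 of 9 and fell in 2, FAP by 1.31 and COL1A1 by 1.87 up (adjusted p = 0.0432; adjusted p = 0.229 with an estimated correlation), and the call ended without NOTCH3 shRNA replicate 1 (0.0839) or 3 (0.0518). Adjusted over the list alone the fibroblast counts were again 5 and 2.

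The lists of the NOTCH pathway and of checkpoint ligands were not called against controls. NOTCH receptors, ligands and core genes rose in 12 of 23 and fell in 6 (the same adjusted over the list alone; adjusted p = 0.128), with NOTCH4 (1.73) and NCSTN (0.33) up and the ligands JAG1 (-0.52) and JAG2 (-0.58) down. NOTCH targets rose in 2 of 13 and fell in 5 (2 and 6 adjusted over the list alone; adjusted p = 0.216): HEY1 (0.54) and CCND1 (0.26) rose, HES2 (-1.37) and MYC (-0.30) fell. Checkpoint ligands rose in 3 of 14 and fell in 5 (4 and 6 adjusted over the list alone; adjusted p = 0.227), with PDCD1LG2 (0.66) and CD276 (0.41) up and LGALS9 (-3.48), TNFSF4 (-2.86) and CD47 (-0.49) down. NF-kB and cytokine genes went both ways (11 up, 9 down of 27; the same adjusted over the list alone; adjusted p = 0.743), with CCL20 (0.93), IL1A (0.90) and IL1B (0.81) up, BIRC3 (-2.33) and CSF2 (-2.03) down and CCL2 at least 257-fold lower. Basal markers (4 up, 6 down of 12; adjusted p = 0.117) included TP63 (-7.17) and ITGB4 (-4.76). Matrix proteases (13 up, 8 down of 24; adjusted p = 0.0661) reached an adjusted p of 0.0464 without control replicate 1, and mitochondrial mRNAs (1 up, 0 down of 13; adjusted p = 0.216) reached 0.0477 without control replicate 3. DNA replication (8 up, 7 down of 33; adjusted p = 0.87), lung metastasis-associated genes (8 up, 5 down of 16; adjusted p = 0.112) with ROBO1 (2.55) up and EREG (-2.40) down, leukocyte markers (7 up, 5 down of 12; adjusted p = 0.839) and endothelial markers (5 up, 2 down of 9; adjusted p = 0.174) with TIE1 (1.5) up and CDH5 (-4.80) down were not called either. Adjusted over the list alone the counts of these last lists were the same, except 9 DNA replication and 6 endothelial genes up.

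In the cells labelled PD-L1 shRNA most listed proliferation, cholesterol and epithelial genes were below 1GXLM controls, and some cytokine genes were above them. All 30 mitosis genes fell, as they also did adjusted over the list alone, with the transcription factor FOXM1 down by 0.84, ANLN by 0.85 and CCNB2 by 0.73 on the log2 scale. DNA replication genes fell in 30 of 33 and rose in 0 (31 and 0 adjusted over the list alone), thymidylate synthase TYMS by 0.91, POLE2 by 0.71 and MCM7 by 0.58. The cytokine gene IL1B rose from 721 ± 28.7 to 2560 ± 40.3 CPM (log2 1.82, SE 0.045), cyclooxygenase PTGS2 rose by 1.52 and IL1A by 1.41, while the chemokine gene CCL2 fell by 7.37. The sulfotransferase SULT1B1 rose 222-fold, from 0.108 ± 0.0859 to 23.3 ± 1.49 CPM, and the metalloprotease ADAMTS9 from 21 ± 0.305 to 236 ± 5.3 CPM (log2 3.48, SE 0.050, adjusted p = 3.82e-19).

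Of 21450 genes 8683 were called, 4147 higher and 4536 lower, and 1827 changed at least 2-fold (713 up, 1114 down). Other genes among the largest increases were ST18 (log2 4.68), CDH12 (4.47), IGFN1 (3.59), GALNT9 (3.58), the focal adhesion gene TNS1 (3.46), DNER, which encodes a Delta/Notch-like EGF-related receptor (3.36, SE 0.069), OLFM2 (2.96) and CACNG7 (2.88). Among the largest decreases were ACKR3, the atypical receptor for CXCL12 (at least 180-fold), the activin subunit INHBB (-8.18, SE 0.23), NLRP2 (-7.71), HLA-DOA (-8.33), HLA-DQB1 (-8.04), HLA-DRB6 (-7.82) and HLA-DRA (-7.75, SE 0.091), the HLA values again uncertain for shared reads. The proprotein convertase PCSK6 had 1 count left (ratio 552, interval 106 to 23500), E-cadherin CDH1 had 2 against 763 in controls (log2 ratio 8.58, interval 6.70 to 11.61), and the actin nucleator COBL had 2 (ratio 258, interval 75.6 to 2270).

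The fall of mitosis and DNA replication genes gave camera adjusted p values of 2.85e-13 and 8.16e-12, and adjusted p = 0.164 and 0.152 with an estimated correlation. Cholesterol genes fell in 22 of 25 and rose in 0, the same adjusted over the list alone, with the squalene synthase FDFT1 (-0.93). Camera gave cholesterol genes an adjusted p of 5.81e-09, and adjusted p = 0.1 with an estimated correlation. Epithelial markers fell in 22 of 28 and 1, CLDN1 (0.30), rose (23 and 1 adjusted over the list alone), with LSR (-5.36), KRT19 (-5.22) and SPINT1 (-3.12) down. For epithelial markers the adjusted p was 1.8e-12, and adjusted p = 0.00699 with an estimated correlation. Basal markers fell in 9 of 12, TP63 by 6.01, ITGB4 by 3.68 and LAMA3 by 1.91, and LAMB3 (0.64) rose (the same counts adjusted over the list alone; adjusted p = 0.000327; adjusted p = 0.0341 with an estimated correlation). Type I interferon genes fell in 20 of 34 and rose in 5, the same adjusted over the list alone, with BST2 (-3.79), IFI27 (-3.76) and XAF1 (-1.86) down and IFI6 (1.55) and IFI44L (1.14) up. Camera gave interferon genes an adjusted p of 0.000569, and adjusted p = 0.194 with an estimated correlation.

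Mesenchymal markers rose in 16 of 26 and fell in 4, the same adjusted over the list alone, with COL6A3 (0.94) and LOX (0.86) up and S100A4 (-4.91) and vimentin VIM (-0.40) down. For mesenchymal markers the adjusted p was 0.00185, and adjusted p = 0.194 with an estimated correlation. NF-kB and cytokine genes rose in 14 of 27 and fell in 6 (15 and 7 adjusted over the list alone), with BIRC3 (-2.25) and CSF2 (-2.27) among those that fell. Camera gave cytokine genes an adjusted p of 0.0163, and adjusted p = 0.203 with an estimated correlation. Lung metastasis-associated genes rose in 10 of 16 and fell in 4, the same adjusted over the list alone, with IL13RA2 (1.44) up and EREG (-1.51) down. For lung metastasis-associated genes the adjusted p was 0.00267, and adjusted p = 0.164 with an estimated correlation. Stemness markers fell in 10 of 18 and rose in 4 (12 and 4 adjusted over the list alone), CD24 by 7.02 and SOX4 by 0.94, with ALDH1A3 (1.34) and CD44 (0.50) up. Camera gave stemness markers an adjusted p of 0.00398, and adjusted p = 0.164 with an estimated correlation. Matrix proteases and inhibitors rose in 14 of 24 and fell in 6 (14 and 7 adjusted over the list alone), MMP1 (2.35), TIMP1 (1.39) and ADAM12 (1.19) up and TIMP3 (-3.85) and PLAT (-1.58) down. For matrix proteases the adjusted p was 0.0228, and adjusted p = 0.367 with an estimated correlation, and 0.0576 without PD-L1 shRNA replicate 2. Stress response genes rose in 15 of 29 and fell in 4, the same adjusted over the list alone, with DDIT4 (0.53) and CEBPB (0.52) up and PDIA4 (-0.95) down (adjusted p = 0.0416; adjusted p = 0.194 with an estimated correlation). The stress response call ended without control replicate 3 (0.0511) or PD-L1 shRNA replicate 1 (0.0549) or 2 (0.0655). Fibroblast markers rose in 6 of 9 and fell in 1, the same adjusted over the list alone (adjusted p = 0.047; adjusted p = 0.164 with an estimated correlation). Without control replicate 1 or 3 this p was 0.0604 or 0.0552, and without PD-L1 shRNA replicate 2 or 3 it was 0.0526 or 0.0527.

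Among the lists not called in these cells, NOTCH receptors, ligands and core genes rose in 9 of 23 and fell in 5 (10 and 5 adjusted over the list alone; adjusted p = 0.153), with NOTCH4 (1.96) and NCSTN (0.42) up and JAG2 (-1.80), JAG1 (-0.56) and the transcription factor RBPJ (-0.38) down. NOTCH targets rose in 1 of 13, which was NOTCH3 itself (1.88), and fell in 4 (adjusted p = 0.208), HES2 (-1.48) and MYC (-0.32) among the latter. NOTCH3 is also among the 9 core genes that rose. Checkpoint ligands rose in 4 of 14 and fell in 6 (adjusted p = 0.119). Among them NT5E (0.31) was up, and LGALS9 (-4.32), TNFSF4 (-2.51) and the targeted CD274 (-0.91) were down. MHC class I genes rose in 6 of 18 and fell in 2 (6 and 3 adjusted over the list alone), HLA-B (0.95), NLRC5 (0.75) and TAP1 (0.39) up, at an adjusted p of 0.05 that became 0.0366 without control replicate 1, 0.0489 without control replicate 2 and 0.0243 without PD-L1 shRNA replicate 3. Hypoxia genes went both ways (9 up, 7 down of 30; adjusted p = 0.693), with PFKFB4 (0.60) up and ALDOC (-2.82) down. YAP/TAZ targets (6 up, 11 down of 24; adjusted p = 0.0696), mitochondrial mRNAs (1 up, 1 down of 13; adjusted p = 0.846), leukocyte markers (5 up, 4 down of 12; adjusted p = 0.904) with CD74 (-6.62) down, and endothelial markers (3 up, 4 down of 9; adjusted p = 0.812) were not called, and adjusted over the list alone their counts were the same, except 7 YAP/TAZ genes up.

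The cells labelled NOTCH3 shRNA were also set against those labelled PD-L1 shRNA, where of the 6 lists called only hypoxia and glycolysis kept the call with an estimated correlation. DNA replication genes were higher in 30 of 33 and lower in 0 (32 and 0 adjusted over the list alone), with TYMS (0.79), RRM2 (0.60) and MCM4 (0.54), and mitosis genes were higher in 29 of 30 and lower in 0 (29 and 0 adjusted over the list alone), with FOXM1 (0.71) and CCNB2 (0.44). Their adjusted p values were 5.6e-14 and 1.74e-12, and adjusted p = 0.127 and 0.304 with an estimated correlation. Hypoxia and glycolysis genes were lower in 25 of 30 and higher in 0 (26 and 0 adjusted over the list alone), with ALDOC at -1.77, PFKFB4 at -1.12 and NDRG1 at -0.82. Camera gave hypoxia genes an adjusted p of 7.45e-11, and adjusted p = 0.0123 with an estimated correlation. Type I interferon genes were higher in 21 of 34 and lower in 2 (23 and 2 adjusted over the list alone), with OAS1 (1.45), OAS3 (1.12) and MX1 (1.01) up and BST2 (-0.63) down. For interferon genes the adjusted p was 1.67e-09, and adjusted p = 0.124 with an estimated correlation. Of the NF-kB and cytokine genes 13 of 27 were lower and 5 higher (14 and 6 adjusted over the list alone): IL11 stood at 65.6 ± 5.34 against 327 ± 30.9 CPM, PTGS2 changed by -1.54 and IL1B by -1.01. Camera gave cytokine genes an adjusted p of 0.0147, and adjusted p = 0.343 with an estimated correlation. Cholesterol genes were higher in 13 of 25 and lower in 1 (the same adjusted over the list alone), ACAT2 (0.51) and SC5D (0.49) up and TM7SF2 (-1.0) down. For cholesterol genes the adjusted p was 0.00205, and adjusted p = 0.343 with an estimated correlation.

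In that comparison 7667 of 21450 genes were called, 3780 higher and 3887 lower in the NOTCH3 shRNA libraries, 1294 of them at least 2-fold. NOTCH3 itself was lower (log2 -1.84, adjusted p = 5.21e-07) and CD274 higher by 0.59 (adjusted p = 3.72e-06). GALNT14 was at least 631-fold and ANO5 at least 183-fold higher, followed by NAP1L2 (7.99), SSX1 (6.38), LBH (5.39) and the chemokine receptor CXCR4 (4.55, SE 0.19), and MMP1 (1.85) and MMP3 (1.87) were higher as well. SULT1B1 (-8.27), the secreted serpin SERPINF1 (-4.78), the Nodal inhibitor LEFTY1 (-3.26) and the EGF receptor ligand AREG (-2.51) were lower, as were the matrix genes LUM (-3.12) and FN1 (-1.16). The other 16 lists were not called, with a smallest adjusted p of 0.193 for leukocyte markers.

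**Figure D2:**
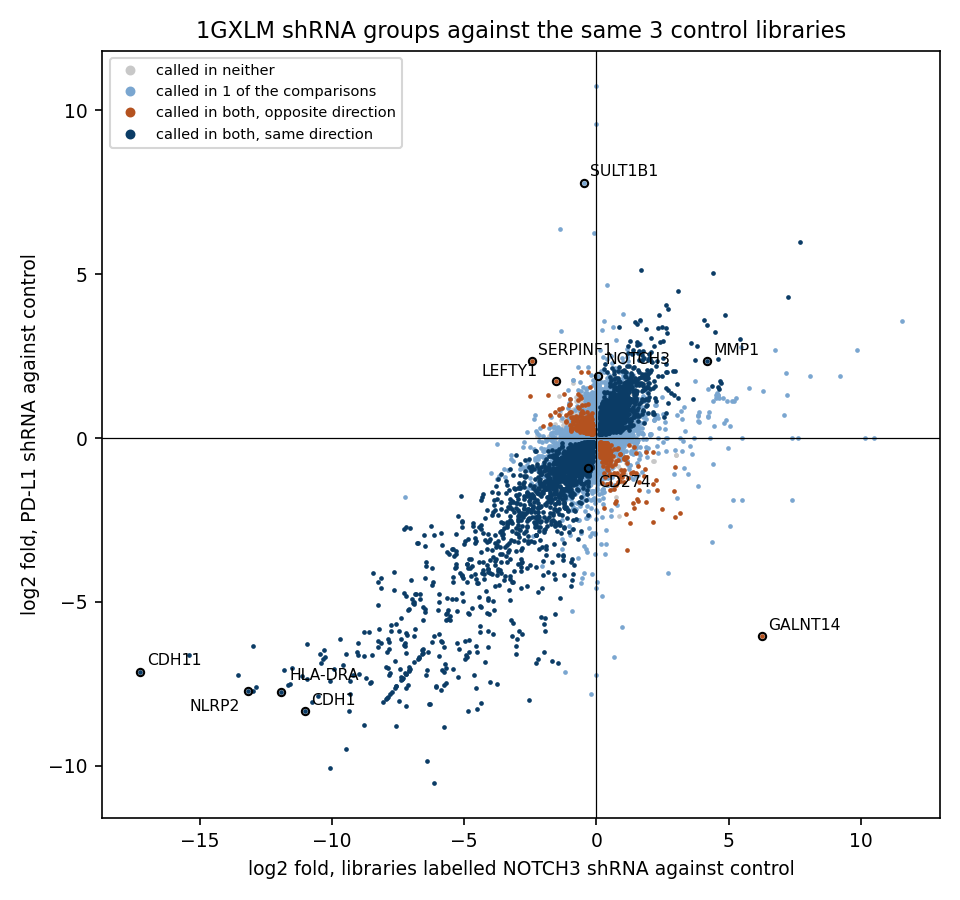
Log2 change against 1GXLM controls of each gene tested in the libraries labelled NOTCH3 shRNA (x axis) and PD-L1 shRNA (y axis). Of the genes called in both comparisons, 1962 lie in the upper right, 2460 in the lower left and 547 in the other quadrants. For a gene with no count in a group the plotted value depends on the prior count of the fit.

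The 2 shRNA groups shared more calls than independent lists of the same sizes would. Of the genes that rose, 1962 were shared (731 from n1 × n2/N), 51.9% of those raised in the NOTCH3 shRNA libraries, and of the genes that fell 2460 were shared (881 from n1 × n2/N), or 59%. CD24, LGALS9, KRT19, TP63, S100A4, TIMP3, HLA-DRA and CD74 fell in both, and MMP1, NOTCH4, IL1B and FAP rose in both, whereas 547 genes were called in opposite directions. Both comparisons use the same 3 control libraries, which cannot be divided further. The log2 changes had r = 0.767 across the 21450 genes (simulated 0.509) and a covariance of 0.799, against 0.0243 in simulations in which only the shared controls linked the groups; genes are not independent replicates. These simulations drew every group from the control mean, so their 0 shared calls do not bear on those of the data. They model noise among the control libraries, not a control population that differs as a whole from both shRNA groups. The covariance with the AV535 response of the same line was 0.024 for NOTCH3 shRNA (simulated 0.0241) and 0.0265 for PD-L1 shRNA (simulated 0.0241), so neither exceeded what shared controls give by more than 0.00244.

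**Figure D3:**
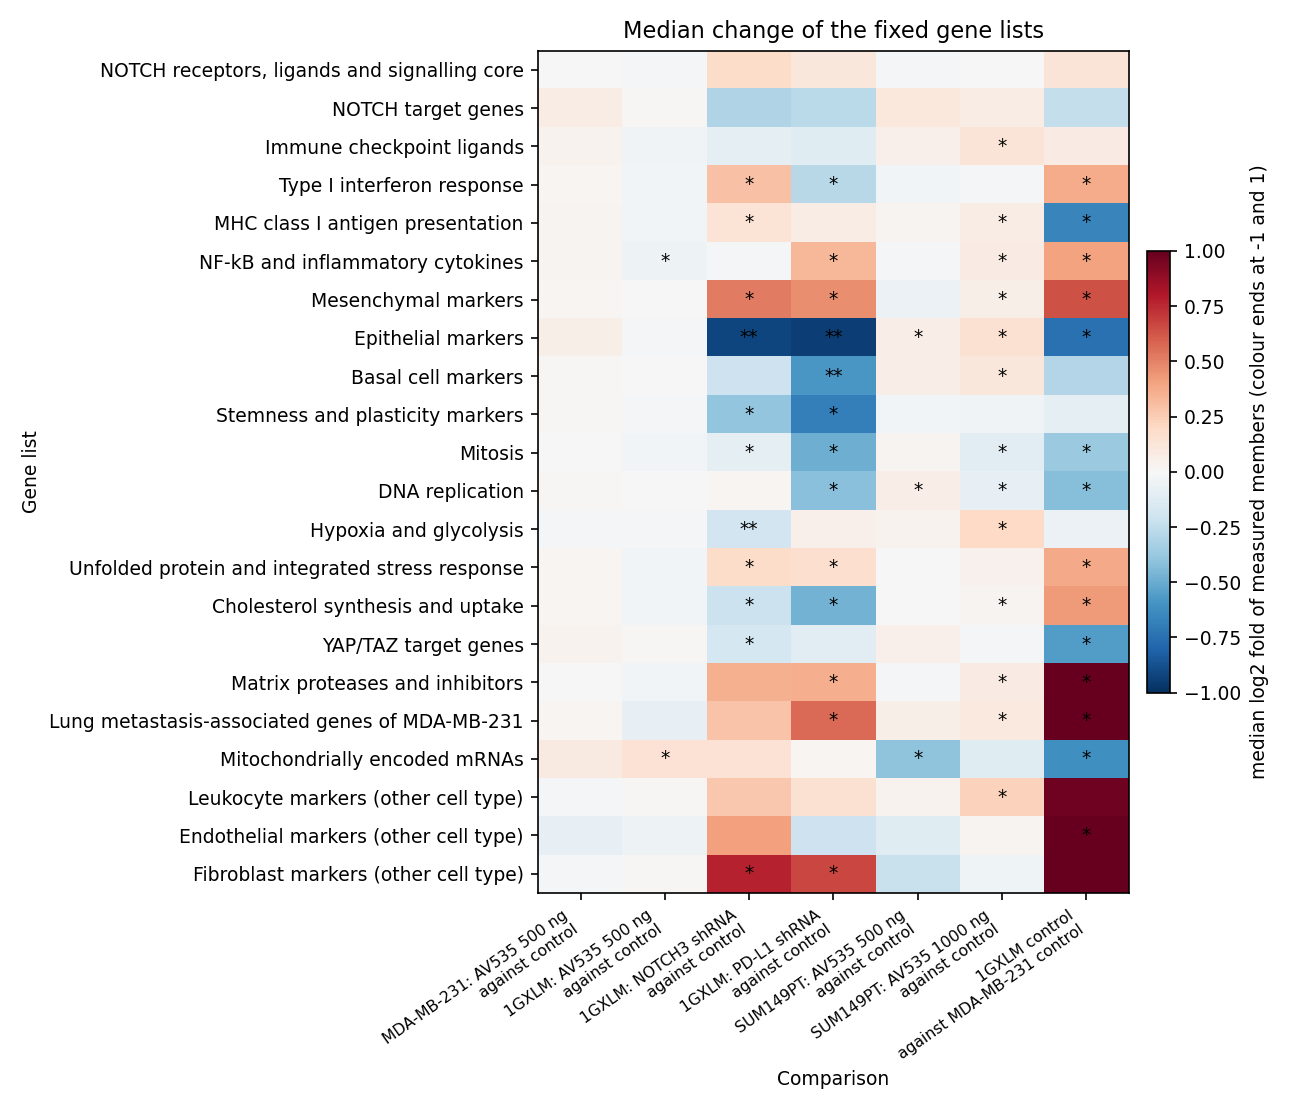
Median log2 change (colour) of the measured members of each of the 22 gene lists (y axis) in the comparisons with controls and of the controls of 1GXLM and MDA-MB-231 (x axis); a single asterisk marks a camera adjusted p under 0.05 and a double asterisk a call that also held with an estimated correlation. Epithelial markers in both shRNA groups carry the double mark, and the NOTCH lists carry none in these comparisons.

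Changes in the shRNA groups were not spread evenly over the chromosomes. In the NOTCH3 shRNA libraries, chromosome 7 had a median log2 change of -0.145 with 72.9% of 657 genes below 0 and 8 of 8 windows below 0, chromosome 3 had -0.155 with 73.3% of 741 genes below 0, and chromosome 22 had 0.122 with 71.8% of its genes above 0. In the PD-L1 shRNA libraries chromosome 7 had -0.129 and chromosome 4 -0.135, with 8 of 8 and 9 of 10 windows below 0. The SD of window medians was 0.117 and 0.104 in these groups against 0.0141 after AV535 in the same line. Shuffled genes gave upper percentiles of 0.042, 0.0454 and 0.00873. The AV535 value too was above the upper percentile of its shuffles, as were those of SUM149PT at 500 ng (0.0257 against 0.0175) and 1000 ng (0.0318 against 0.0163). For the controls of 1GXLM and MDA-MB-231 the SD was 0.267 against 0.1. Both shRNA comparisons use the same controls, so a shift common to both can also lie in the controls. NOTCH3 shRNA against PD-L1 shRNA, a contrast without these controls, gave an SD of 0.0916 against 0.0424. There chromosome 7 had a median of -0.00576, chromosome 3 of -0.19 and chromosome 4 of 0.162.

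**Figure D4:**
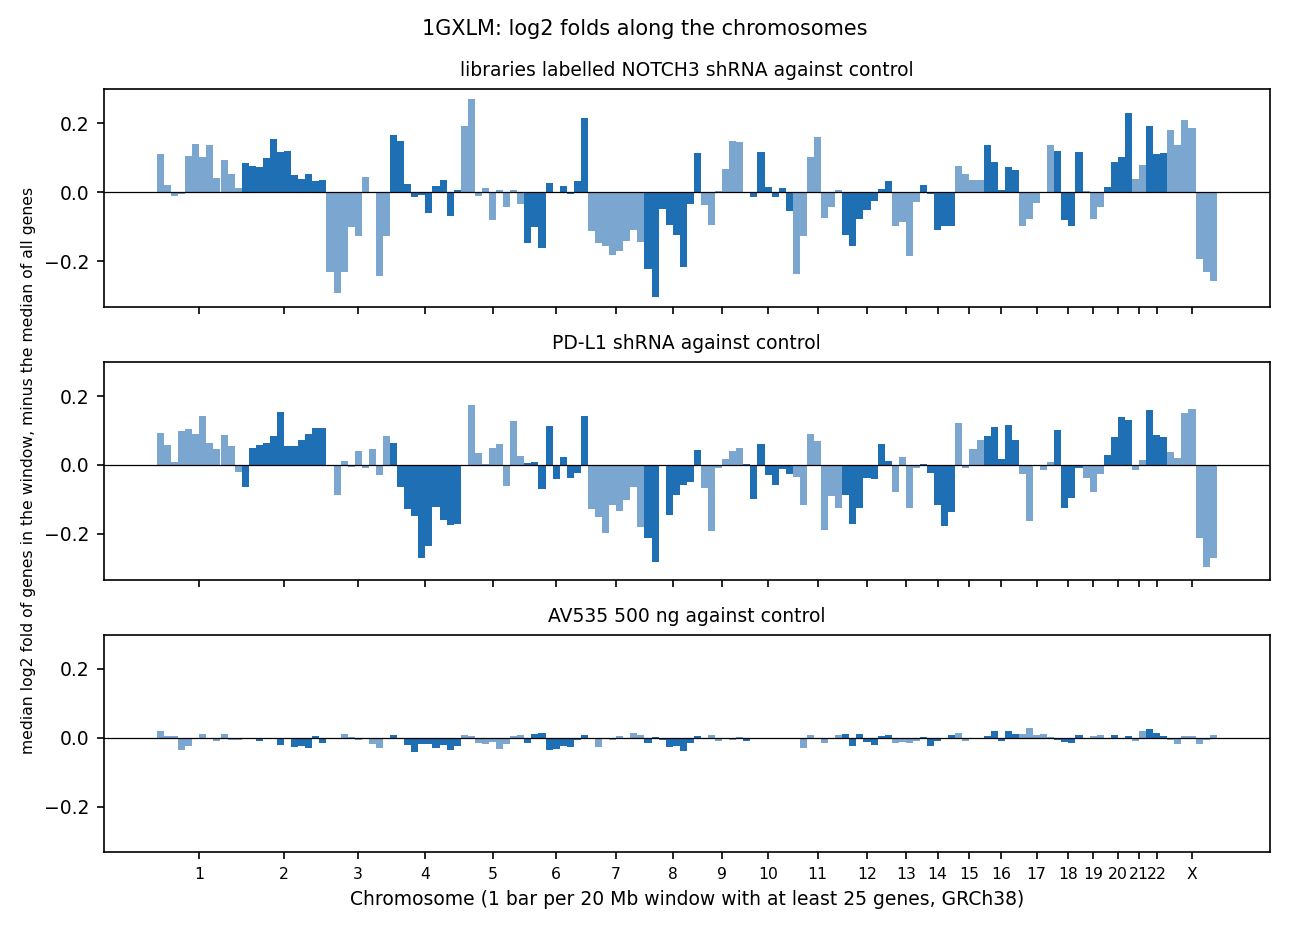
Bars give the median log2 change against 1GXLM controls, minus the median of all genes (y axis), in windows of 20 Mb along the chromosomes (x axis) for the NOTCH3 shRNA, PD-L1 shRNA and AV535 libraries. The medians of chromosome 7 lie below 0 in all 8 windows of both shRNA groups, and the AV535 medians stay near 0 (SD 0.0141).

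The NOTCH3 shRNA libraries were also compared directly with the AV535 libraries of 1GXLM, AV535 being taken as the NOTCH3 antibody of the design text. The same genes that separated the NOTCH3 shRNA libraries from controls stood out: CDH11 was at least 20100-fold and MUC5B at least 6390-fold lower, NLRP2 at least 1190-fold and AGR2 at least 979-fold, and ANO5 was at least 178-fold higher, with GALNT14 (5.93) and EPB41L3 (5.32) higher too. NAP1L2 and SSX1 each had 2 counts in the AV535 libraries, giving ratios of 449 (interval 151 to 4520) and 416 (118 to 3520). In total 7920 of 21450 genes were called (3857 up, 4063 down; 1765 at least 2-fold). Epithelial markers were lower in 24 of 28 and higher in 0 (25 and 0 adjusted over the list alone; adjusted p = 6.51e-14; adjusted p = 0.00442 with an estimated correlation) and hypoxia genes lower in 17 of 30 and higher in 1 (20 and 2 adjusted over the list alone; adjusted p = 9.09e-06; adjusted p = 0.0436 with an estimated correlation). Another 7 lists were called by camera and lost the call with an estimated correlation. Higher were interferon (19 up, 10 down of 34; adjusted p = 0.0292; adjusted p = 0.416 with an estimated correlation), MHC class I (9 up, 2 down of 18; 0.0125; 0.265), mesenchymal (16 up, 5 down of 26; 0.00156; 0.265) and stress response genes (17 up, 2 down of 29; 0.00296; 0.184). Lower were stemness (3 up, 10 down of 18; 0.0274; 0.265), cholesterol (1 up, 13 down of 25; 0.00155; 0.265) and YAP/TAZ genes (4 up, 12 down of 24; 0.0242; 0.416). Adjusted over the list alone the counts were 20 interferon and 11 MHC class I genes and 2 cholesterol genes up, and otherwise as given. The interferon call ended without NOTCH3 shRNA replicate 1 (0.0628), and the stemness and YAP/TAZ calls without NOTCH3 shRNA replicate 3 (each 0.0592). Mitosis (0.0615; 1 up, 8 down of 30) passed without AV535 replicate 1 (0.0347) or NOTCH3 shRNA replicate 2 (0.00865). Lung metastasis-associated genes (0.0614) passed without AV535 replicate 1 (0.0487) or 3 (0.0399) or NOTCH3 shRNA replicate 1 (0.0463). Fibroblast markers (0.0635) passed without AV535 replicate 1 (0.0487) or NOTCH3 shRNA replicate 2 (0.0471), and matrix proteases (0.0615) without the latter (0.048). NOTCH3 differed by 0.037 and CD274 by -0.21 (adjusted p = 0.0205), a call that ended without AV535 replicate 1 (0.0503) or 3 (0.0728) or NOTCH3 shRNA replicate 1 (0.0633) or 3 (0.0649).

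In 1GXLM, AV535 left the genes of the NOTCH pathway near their control level. HES1, a direct NOTCH target, changed by a log2 of -0.026 (SE 0.087), HEY1 by -0.090 (SE 0.15), JAG1 by -0.006 and MYC by -0.015. The NOTCH core and target lists had adjusted p values of 0.901 and 0.94, and checkpoint ligands 0.398. The edgeR test called 0 of 21450 genes, with 482 (2.25%) at an unadjusted p under 0.05. That is below the share of 0.05 that evenly spread p values would give. DESeq2 and limma-voom also called 0, with 429 and 480 at that p. Without a filter on low counts 1 gene was called. Camera called the NF-kB list downwards (adjusted p = 0.00559; median -0.052; adjusted p = 0.968 with an estimated correlation), with BIRC3 at -0.049, CCL20 at -0.13 and IL1B at -0.030. It called mitochondrial mRNAs upwards (adjusted p = 0.0214; median 0.14; adjusted p = 0.968 with an estimated correlation), with MT-CO1 at 0.12. No member of either list was called, also adjusted over the list alone. The NF-kB call ended without AV535 replicate 2 (0.186) or control replicate 2 (0.0636), and the mitochondrial one without AV535 replicate 1 (0.778) or 2 (0.212) or control replicate 1 (0.953) or 2 (0.0636). Without control replicate 3, hypoxia (0.0136) and matrix proteases (0.0381) passed, and without AV535 replicate 3 mitosis did (0.0132).

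In MDA-MB-231, where NOTCH3 stood near 1 CPM, AV535 gave no called gene and no called list. HES1 changed by 0.17 (SE 0.16), HEY1 by -0.99 (SE 0.45) and NOTCH1 by 0.39 (SE 0.24), each with an adjusted p of 1. The edgeR test found 0 of 20166 genes, with 0.62% of them at an unadjusted p under 0.05, also below a share of 0.05. DESeq2 and limma-voom found 0. Each had genes at that p amounting to 0.679% of these 20166, but DESeq2 was run on all genes with a count. The NOTCH core, NOTCH target and checkpoint lists each had an adjusted p of 0.856, and the smallest over the 22 lists was 0.781. Without AV535 replicate 1 the mitochondrial list passed (0.00214). Control replicate 2 and AV535 replicate 1 stood apart from the other 4 libraries on the first principal component, which held 64.5% of the variance, and had 7.16% and 6.75% of their counts in ribosomal protein genes against 4.37% to 4.83% in the others. Without these 2 libraries the count was 0, with 1369 genes at an unadjusted p under 0.05. Precision was low here: of 50 genes changed 2-fold in simulated data 8 were recovered.

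In SUM149PT, the line with the most NOTCH3, AV535 at 500 ng gave small shifts that did not pass gene by gene. HES1 changed by 0.18 (SE 0.073, adjusted p = 0.256), NRARP by 0.22, NOTCH1 by 0.24 and MYC by 0.12, and the NOTCH core and target lists had adjusted p values of 0.82 and 0.324. Of the epithelial list, CLDN4 at 0.26, JUP at 0.24, CLDN7 at 0.19 and LSR at 0.28 did not pass (each adjusted p = 0.128). Camera called this list upwards (adjusted p = 0.000104; adjusted p = 0.79 with an estimated correlation) with a median of 0.064, 0 members called and 9 adjusted over the list alone. DNA replication genes were called upwards (adjusted p = 0.000107; adjusted p = 0.79 with an estimated correlation) with CDT1 at 0.46 and UHRF1 at 0.26. Mitochondrial mRNAs were called downwards with a median of -0.40 (adjusted p = 0.000174; adjusted p = 0.79 with an estimated correlation) with MT-CO1 at 7620 against 9900 CPM. In these last 2 lists no member was called, also adjusted over the list alone. Across 13963 genes the log2 change at this dose followed gene length (Spearman correlation -0.33), and the lists were not tested again with that trend removed. Without 500 ng replicate 3 the lists of mitosis (0.00772), basal markers (0.00913), hypoxia (0.0343), lung metastasis-associated genes (0.0373) and MHC class I (0.0437) passed too, and mitosis passed without control replicate 3 (0.000456). The edgeR test called 0 of 22600 genes, with 3705 (16.4%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. This share is above 0.05 and above the 9.66% found at 1000 ng. DESeq2 called 836 (496 up, 340 down), and without a filter on low counts edgeR called 485.

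The genes called in SUM149PT at 1000 ng rose by less than 2-fold, and some of them respond to hypoxia or encode keratins. The vasodilator peptide gene adrenomedullin, ADM, rose from 30.3 ± 3.35 to 48.3 ± 2.74 CPM (log2 0.66, SE 0.073, adjusted p = 0.00785) and CA9 from 30.1 ± 3 to 44.2 ± 3.28 CPM (log2 0.55, SE 0.071, adjusted p = 0.00855). Keratins KRT19 (298 to 410 CPM, log2 0.45, adjusted p = 0.0192) and KRT17 (0.35), the small GTPase RHOB (0.52), the transcription factor FOXQ1 (0.58), the morphogen SHH (0.68) and C1QL1 (0.88) rose as well, in 3 of 3 libraries above all controls. NOTCH genes did not pass: HES1 was at 0.16 (SE 0.073, adjusted p = 0.518), NRARP at 0.024 and HEY1 at -0.011, with list adjusted p values of 0.354 for the core and 0.159 for the targets (0.0265 without 1000 ng replicate 2).

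The edgeR test called 23 of 22600 genes at this dose, all higher, none of them 2-fold, with 2183 at an unadjusted p under 0.05. DESeq2 called 305 (270 up, 35 down), which included the 23. The count was 0 without 1000 ng replicate 3, 1 without control replicate 3, 10 without control replicate 1 or 1000 ng replicate 2, 17 without 1000 ng replicate 1 and 49 without control replicate 2. Without 1000 ng replicate 3 the adjusted p of ADM became 0.0819, of RHOB 0.0583, of FOXQ1, KRT17 and C1QL1 0.089, and of SHH, CA9 and KRT19 0.0893. Without control replicate 3 it was 0.0717 for RHOB, FOXQ1, KRT17, C1QL1 and SHH, 0.097 for CA9 and 0.122 for KRT19. CA9 was also lost without 1000 ng replicate 2 (0.057), and KRT19 without that library (0.0904) and without control replicate 1 (0.108) or 2 (0.055).

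Hypoxia and glycolysis was the list with the lowest camera p at 1000 ng: 3 of 30 members were called and 26 adjusted over the list alone, all upwards. Among them ALDOA was at 0.25, EGLN3 at 0.60 (adjusted p = 0.0925), ANGPTL4 at 0.44 and SLC2A1 at 0.28. Camera gave hypoxia genes an adjusted p of 1.08e-21 (median 0.20), and adjusted p = 0.0987 with an estimated correlation (fry adjusted p = 0.00632). The single-gene call of ALDOA (adjusted p = 0.0406) ended without any 1 of the 6 libraries. Without control replicates 1, 2 and 3 it was 0.129, 0.091 and 0.315, and without 1000 ng replicates 1, 2 and 3 it was 0.139, 0.262 and 0.376. Epithelial markers (2 called, 15 adjusted over the list alone; adjusted p = 4.59e-10), basal markers (1 and 6; 6.66e-06), MHC class I (0 and 7; 0.000133), leukocyte markers (0 and 2; 0.00039) with CD68 at 0.25, and checkpoint ligands (0 and 4; 0.00583) were called upwards, each with an adjusted p = 0.0987 with an estimated correlation. The leukocyte list also holds the MHC class II genes CD74 (0.89) and HLA-DRA (0.87), which were not called. Lung metastasis-associated genes (0 and 3; adjusted p = 0.00098; adjusted p = 0.163 with an estimated correlation) were called upwards as well. Mitosis genes were called downwards (adjusted p = 5.15e-08; adjusted p = 0.364 with an estimated correlation), with 0 called, 2 adjusted over the list alone, ASPM at -0.19 and CENPE at -0.21. DNA replication genes were called downwards too, with 0 and 0 members (adjusted p = 3.51e-06; adjusted p = 0.372 with an estimated correlation).

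Several other lists were called upwards at 1000 ng with members on both sides of 0. Mesenchymal markers had a median of 0.062 and a mean of -0.25, and matrix proteases a median of 0.081 and a mean of -0.23 (each adjusted p = 0.00477; adjusted p = 0.364 with an estimated correlation). The mesenchymal call ended without control replicate 2 (0.103), and the matrix call without control replicate 2 (0.0886) or 3 (0.0804). In control replicate 1 of this line VIM stood at 91.4 CPM on raw totals, against 40.1 to 45.5 CPM in the other 8 libraries. NF-kB genes (adjusted p = 0.00579; adjusted p = 0.364 with an estimated correlation) lost the call without 1000 ng replicate 1 (0.235). Cholesterol genes (adjusted p = 0.0219; adjusted p = 0.465 with an estimated correlation) lost it without that library (0.137) or control replicate 1 (0.128) or 3 (0.0527). Adjusted over the list alone, 6 mesenchymal, 1 matrix, 1 NF-kB and 0 cholesterol genes passed. Mitochondrial mRNAs, not called with all libraries (0.0666), passed downwards without control replicate 3 (0.00676) or 1000 ng replicate 1 (0.00605) or 2 (0.0481).

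Between the 2 doses no single gene passed in edgeR, and the camera calls of hypoxia genes (higher at 1000 ng) and of DNA replication and mitosis genes (lower) were lost with an estimated correlation. ADM differed by a log2 of 0.53 (adjusted p = 0.0701), CA9 by 0.37 (0.145) and ANKRD37 by 0.41. Adjusted over the list alone 22 of 30 hypoxia genes passed upwards, while 28 of 33 DNA replication genes and 15 of 30 mitosis genes passed downwards, with PCNA at -0.20, POLE2 at -0.19, CCNA2 at -0.22 and UBE2C at -0.17. The camera adjusted p values were 2.88e-17, 1.84e-17 and 8.49e-14, and adjusted p = 0.283, 0.322 and 0.371 with an estimated correlation. Gene by gene, edgeR called 0 of 22600, with 2617 at an unadjusted p under 0.05. DESeq2 called 211 (175 up, 36 down), and edgeR without a filter 117. The lists of mitochondrial mRNAs (0.0138), leukocyte markers (0.0138), matrix proteases (0.0343), mesenchymal markers (0.0391), NF-kB genes (0.0415) and fibroblast markers (0.0415) were called upwards, with adjusted p = 0.591, 0.283, 0.516, 0.516, 0.516 and 0.385 with an estimated correlation, and 0, 3, 0, 2, 0 and 0 members adjusted over the list alone. Each of these 6 calls ended without at least 1 library. Without 500 ng replicate 1 these were mitochondrial mRNAs (0.169) and fibroblast markers (0.107). Without 500 ng replicate 2 they were matrix proteases (0.0789), mesenchymal markers (0.145), NF-kB genes (0.145) and fibroblast markers (0.114), and without 500 ng replicate 3 matrix proteases (0.207), mesenchymal markers (0.0507) and NF-kB genes (0.126). Without 1000 ng replicate 1 the calls of mitochondrial mRNAs (0.0887), NF-kB genes (0.379) and fibroblast markers (0.0789) ended, without replicate 2 that of matrix proteases (0.0508), and without replicate 3 those of leukocyte markers (0.12), matrix proteases (0.12), mesenchymal markers (0.253) and NF-kB genes (0.0599).

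**Figure D5:**
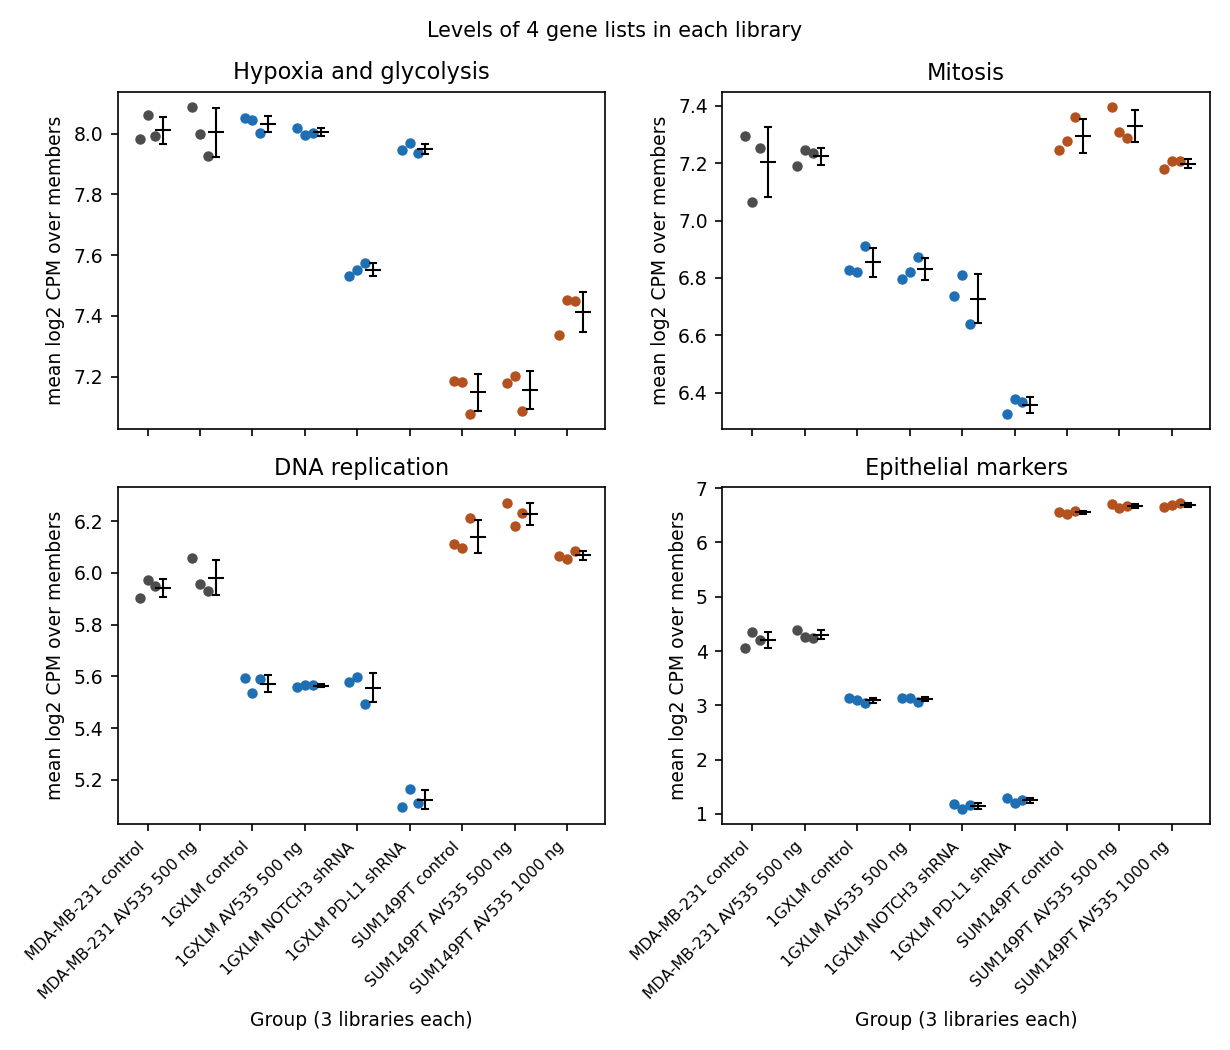
Mean log2 CPM of the members of the hypoxia, mitosis, DNA replication and epithelial lists (y axis) in each library by group (x axis), with points for libraries and ticks and error bars for group means and SD. In SUM149PT the hypoxia genes are highest at 1000 ng, with a median change of 0.198 against controls.

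The control cells of 1GXLM differed from MDA-MB-231 controls in 11337 of 22321 genes (5881 higher, 5456 lower), 4836 of them at least 2-fold (2682 and 2154). NOTCH3 was 8.42-fold higher (log2 3.07, adjusted p = 1.67e-10), and CD274 was not different (-0.008). NOTCH targets were higher in 4 of 13, among them NOTCH3 itself, HEY1 (3.23) and HES1 (2.26), and lower in 5 (4 and 6 adjusted over the list alone; adjusted p = 0.616). NOTCH core genes were higher in 10 of 23, among them MAML3 (3.48), and lower in 5 (the same adjusted over the list alone; adjusted p = 0.179). The gelatinase MMP9 stood at 129 ± 16.9 against 0.254 ± 0.168 CPM, CSF3, the granulocyte growth factor gene, at 399 ± 70.3 against 0.644 ± 0.119 CPM, and IL1B at 721 ± 28.7 against 14.2 ± 0.84 CPM. PAEP (glycodelin) reached 579 ± 37.9 CPM with 2 counts in MDA-MB-231 (ratio 63700, interval 18500 to 553000), MUC5B had 1 count there (ratio 12200, interval 2560 to 562000), ESM1 was at least 1780-fold and FGF13 at least 529-fold higher, and the transforming growth factor coreceptor ENG differed by a log2 of 10.97 (SE 0.21). IQCA1 (at least 263-fold), DACT2 (at least 194-fold), TP53I11 (-9.26), VTN (-8.24), TRIM29 (-7.45) and the interleukin 1 receptor antagonist IL1RN (-6.97) were lower, as was PSG1 (-9.55), whose reads can be shared with other PSG copies. SOX4 (7.43), CD24 (5.85) and LGR5 (5.66) were higher and ABCG2 (-3.92) and CXCR4 (-3.85) lower within the stemness list.

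Matrix proteases were higher in 20 of 24 and lower in 2 (adjusted p = 1.4e-07; adjusted p = 0.0749 with an estimated correlation). Lung metastasis-associated genes, among them PTGS2 (9.19) and MAN1A1 (7.96), were higher in 12 of 17 and lower in 4 with NEDD9 (-4.20) and VCAM1 (-5.31) (0.00152; adjusted p = 0.0645 with an estimated correlation). Endothelial markers, TIE1 (8.86) and PECAM1 (3.11) among them, were higher in 7 of 9 and lower in 1 (0.000655; adjusted p = 0.0822 with an estimated correlation). NF-kB genes (16 up, 7 down of 27; 0.00607), mesenchymal markers (15 up, 5 down of 26; 0.00635) with SNAI1 (3.91) up and AXL (-1.71) down, and cholesterol genes (18 up, 1 down of 25; 0.000655) were higher. Mitosis (1 up, 22 down of 30; 3.95e-05), DNA replication (1 up, 19 down of 33; 4.17e-05), YAP/TAZ targets (3 up, 15 down of 24; 0.000213) with F3 (-3.49), epithelial markers (4 up, 19 down of 29; 0.00146) with MUC1 (-3.22), and MHC class I (3 up, 12 down of 18; 0.00161) with HLA-B (-2.39) were lower. Each of these 8 lists had an adjusted p = 0.145 with an estimated correlation. The mitochondrial list was lower (0 up, 9 down of 13; 0.00329; adjusted p = 0.397 with an estimated correlation). The stress response (17 up, 4 down of 29; 0.00607; adjusted p = 0.178 with an estimated correlation) and interferon lists (18 up, 6 down of 34; 0.0233; adjusted p = 0.233 with an estimated correlation) were higher. Adjusted over the list alone, the counts were 24 mitosis, 16 YAP/TAZ, 8 NF-kB and 2 endothelial genes lower, 16 mesenchymal and 18 stress response genes higher, and 2 cholesterol genes lower, and otherwise as given. The checkpoint (0.752), stemness (0.925) and hypoxia (0.333) lists were, with the NOTCH lists, among the 8 not called. The number of genes depended on no single library: leaving out each gave 9943 to 11891. The log2 change between these controls followed gene length with a Spearman correlation of 0.247 over 13662 genes, and neither genes nor lists were tested with that trend removed.

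The responses to 500 ng of AV535 were also set against each other between the lines. The edgeR test of the difference called 0 genes for 1GXLM minus MDA-MB-231 (374 of 22321 at an unadjusted p under 0.05), 0 for SUM149PT minus MDA-MB-231 (1223 of 24855) and 0 for SUM149PT minus 1GXLM (1216 of 24855). DESeq2 called 2 genes in each of the last 2. Without SUM149PT control replicate 2 edgeR called 17 for SUM149PT minus MDA-MB-231 and 29 for SUM149PT minus 1GXLM. Without SUM149PT control replicate 1 the former count was 1, and without 500 ng replicate 3 the latter was 1. Across genes, the responses of MDA-MB-231 and 1GXLM had r = -0.0293 over 19506 genes. For MDA-MB-231 and SUM149PT r was -0.00546 over 18880, and for 1GXLM and SUM149PT -0.0634 over 19583. Simulated unchanged groups gave 0.00548, -0.00652 and -0.00107 in the same order. Since edgeR called 0 genes in each of these responses, noise can hide a small shared response. The values therefore do not show that the lines respond differently. Within SUM149PT the 2 doses gave r = 0.605, against 0.489 in simulations with shared controls alone, and a covariance of 0.0518 against 0.0259.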

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

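The tests of labelled read totals, chromosome copy number, gene length in MDA-MB-231, RNA of another line in MDA-MB-231, RNA of 1GXLM in a SUM149PT control and single libraries were chosen only after the result was seen.

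Both shRNA groups of 1GXLM differed from their controls in 7947 and 8683 genes, and the NOTCH3 transcript was not lower in the libraries labelled NOTCH3 shRNA. Admixed MDA-MB-231 cells were argued against, since 5 genes abundant in MDA-MB-231 and near 0 in 1GXLM stood at a median of 0.434% of their MDA-MB-231 level in those libraries, against 0.631% with AV535. An exchange of treatments by the labelled read totals was argued against by CD274, which was higher by a log2 of 0.214 (SE 0.0691) in the libraries titled AV535 than in those titled NOTCH3 shRNA. This rests on 1 gene. With each library left out, NOTCH3 shRNA minus AV535 stayed at -0.258 to -0.181. The call ended without AV535 replicate 1 or 3 or NOTCH3 shRNA replicate 1 or 3. What stays open is that the groups may be populations with different chromosome copy numbers. Their SDs of window medians were 0.104 or more, where the upper percentiles of shuffled genes were at most 0.0454. AV535 in 1GXLM (0.0141, upper percentile 0.00873) also exceeded this percentile of its shuffles. So did AV535 in SUM149PT at 500 ng (0.0257, upper percentile 0.0175) and 1000 ng (0.0318, upper percentile 0.0163). The measure is therefore not specific to copy number, which was not measured. The shRNA target, transduction and selection cannot be separated with 1 control group whose kind is not stated, a loss of NOTCH3 protein without loss of the transcript was not measured, and 1 of the 10 splits of the libraries, the real one, gave calls in each shRNA comparison (highest other 0), too few splits for a share under 0.05.

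Hypoxia and glycolysis genes were called upwards in SUM149PT at 1000 ng of AV535 (camera adjusted p = 1.08e-21; adjusted p = 0.0987 with an estimated correlation). A trend with gene length as the whole cause was argued against, since the median after its removal was 0.222 (quartiles 0.156 to 0.29, 29 of 30 genes above 0) against 0.198 before. RNA of 1GXLM in control replicate 1 was argued against by a median of 0.233 without that library, and a single deciding library by a lowest median of 0.177, found without 1000 ng replicate 2. An effect of the antibody dose and a difference in culture state, such as density or medium, both stay open and were not tested. The split count of the 23 single-gene calls was 1 of 10 with 0 as the highest other, too few splits for a share under 0.05.

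Control replicate 2 and AV535 replicate 1 of MDA-MB-231 stood apart from the other 4 libraries of the line. RNA of another line of the study was argued against by median shares of at most 0.148% for 1GXLM and 0.0095% for SUM149PT. The value for 1GXLM rests on only 3 genes, that for SUM149PT on 28. The difference followed gene length, with a Spearman correlation of -0.589 over 11975 genes and medians of 0.417 among the shortest and -0.383 among the longest 25% of them, so a difference in RNA integrity or library preparation may contribute. Removing the trend lowered the SD of the differences from 0.483 to 0.398, so length did not account for all of it. No biological explanation was tested, since the libraries lie in different groups.

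The response to 500 ng of AV535 differed between lines by a test of the difference itself in 6 camera calls on 4 lists, each lost with an estimated correlation, and edgeR called no single gene with all libraries. DESeq2 called 2 for SUM149PT minus MDA-MB-231 and 2 for SUM149PT minus 1GXLM, and without SUM149PT control replicate 2 edgeR called 17 and 29. The response of mitochondrial mRNAs, not their level, was lower in SUM149PT than in MDA-MB-231 (adjusted p = 4.5e-06, median difference -0.473; adjusted p = 0.928 with an estimated correlation). It was also lower than the response in 1GXLM (adjusted p = 1.99e-07, median -0.511; adjusted p = 0.438 with an estimated correlation). The response of DNA replication genes was higher in SUM149PT than in MDA-MB-231 (adjusted p = 0.0218, median 0.0613; adjusted p = 0.945 with an estimated correlation). That call ended without MDA-MB-231 AV535 replicate 2 (0.141) or 3 (0.265), MDA-MB-231 control replicate 2 (0.493), SUM149PT 500 ng replicate 1 (0.486) or SUM149PT control replicate 1 (0.256) or 2 (0.228). Their response was also higher than in 1GXLM (adjusted p = 8e-04, median 0.0917; adjusted p = 0.438 with an estimated correlation; 0.0537 without SUM149PT 500 ng replicate 1). The response of mitosis genes was higher in SUM149PT than in 1GXLM (adjusted p = 0.0104, median 0.0848; adjusted p = 0.542 with an estimated correlation). That call ended without 1GXLM AV535 replicate 1 (0.0586), 1GXLM control replicate 3 (0.112), SUM149PT 500 ng replicate 1 (0.243) or SUM149PT control replicate 1 (0.137). The response of epithelial markers was higher in SUM149PT than in 1GXLM (adjusted p = 0.0351, median 0.15; adjusted p = 0.438 with an estimated correlation). That call ended without 1GXLM AV535 replicate 1 (0.0586) or 3 (0.0701), 1GXLM control replicate 1 (0.0963) or 2 (0.105), SUM149PT 500 ng replicate 1 (0.151) or SUM149PT control replicate 1 (0.0655) or 2 (0.0557).

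Other splits were counted for the remaining comparisons of genes. For AV535 in MDA-MB-231, in 1GXLM and at 500 ng in SUM149PT, and for the 2 doses, all 10 splits gave 0 genes, the real one included, and 10 splits are too few for a share under 0.05. The same limit held for NOTCH3 shRNA against PD-L1 shRNA (7667 genes), NOTCH3 shRNA against AV535 (7920) and the controls of 1GXLM and MDA-MB-231 (11337), with 0 as the highest other. For the differences between responses the real count was 0, which each of the 20 drawn splits equals or exceeds whatever it gives, so the splits do not test chance there. For SUM149PT minus MDA-MB-231 the highest other split gave 4654 genes, a structure of the samples: of 10 splits with both MDA-MB-231 libraries that stood apart in the same group 5 called 2948 to 4654 genes, and of 10 with them in different groups none called more than 1.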

How the results depend on the processing

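No paired analysis was possible because the labels carry no replicate numbers that link cultures across groups. The fits without the 2 libraries of MDA-MB-231 that stood apart (0 genes) and with the ribosomal protein share as a covariate (0 genes) were chosen only after the result was seen. Of 9581 alternative values for named genes, 9376 kept direction and call, 205 lost the call and 0 reversed. These genes were chosen among called genes by large change or low p, so part of this stability is built in. For AV535 at 1000 ng in SUM149PT, 60 of 210 values lost the call, and each of the 14 named genes lost it at least once. Of 3256 values for gene lists, 2972 stayed, 177 lost and 105 gained the call, and 2 reversed. In MDA-MB-231 a 2-fold change was recovered for 8 of 50 simulated genes. The cause of each difference below was not tested, except that fits of fewer or more libraries change the residual degrees of freedom.

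Numbers of genes moved as follows. Without a filter 1 gene was called for AV535 in 1GXLM, 485 at 500 ng and 143 at 1000 ng in SUM149PT, and 117 between doses. The fit of all 27 libraries gave 5035 for NOTCH3 shRNA, 5622 for PD-L1 shRNA, 4472 between them, 5014 for NOTCH3 shRNA minus AV535, 2 at 500 ng, 14 at 1000 ng and 3 between doses. DESeq2 gave 836 at 500 ng, 305 at 1000 ng, 211 between doses, and 2 for SUM149PT minus MDA-MB-231 and 2 for SUM149PT minus 1GXLM. The strict filter gave 48 and the contrast libraries alone 69 at 1000 ng. Leaving out libraries gave 0 to 49 at 1000 ng, 0 to 17 for SUM149PT minus MDA-MB-231 and 0 to 29 for SUM149PT minus 1GXLM. The overlap of the shRNA groups was 999 genes at 2-fold, and that of the SUM149PT doses 67 by DESeq2.

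Numbers of lists called with an estimated correlation were 2 for NOTCH3 shRNA, 2 for PD-L1 shRNA, 1 between them, 2 for NOTCH3 shRNA minus AV535, and 0 for AV535 in 1GXLM, both doses, their difference, the 1GXLM and MDA-MB-231 controls and both responses of SUM149PT. With fry they were 20, 20, 13 and 18 for the first 4, 6 at 1000 ng, 4 between doses, and 0 for AV535 in 1GXLM, for 500 ng and for the responses of SUM149PT. Without a filter they were 5 between doses, 1 for SUM149PT minus MDA-MB-231 and 14 for NOTCH3 shRNA minus AV535, and with relative log expression factors 1 for SUM149PT minus MDA-MB-231. Leaving out libraries gave 0 to 1 for AV535 in MDA-MB-231, 0 to 4 in 1GXLM, 3 to 8 at 500 ng, 5 to 11 between doses, 0 to 2 for 1GXLM minus MDA-MB-231, 1 to 4 for SUM149PT minus MDA-MB-231 and 1 to 5 for SUM149PT minus 1GXLM. By fry the NF-kB list in NOTCH3 shRNA (0.0448) and the hypoxia list in PD-L1 shRNA (0.00739) reversed.

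Uncalled log2 changes of the targeted genes crossed 0 when libraries were left out. NOTCH3 ranged from -0.086 to 0.135 for AV535 in 1GXLM, -0.049 to 0.188 for NOTCH3 shRNA, -0.03 to 0.048 between doses, -0.209 to 0.033 for SUM149PT minus MDA-MB-231, -0.01 to 0.219 for SUM149PT minus 1GXLM and -0.044 to 0.177 for NOTCH3 shRNA minus AV535. CD274 ranged from -0.149 to 0.065 for AV535 in MDA-MB-231, -0.192 to 0.103 between doses, -0.153 to 0.081 between controls (0.084 with raw totals), -0.166 to 0.053 for 1GXLM minus MDA-MB-231 and -0.272 to 0.014 for SUM149PT minus 1GXLM; for NOTCH3 shRNA minus AV535 it ranged from -0.258 to -0.181.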

Other observations

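The list of MHC class II genes in the first paragraph was chosen only after its values were seen, and no test of it was planned.

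MHC class II genes, which present peptides to helper T cells, fell in both shRNA groups of 1GXLM. Of 12 genes 11 fell in the libraries labelled NOTCH3 shRNA and 11 in those labelled PD-L1 shRNA. CIITA, their master regulator, stood at 17.2 CPM in controls, 0.0293 CPM in the former and 0.115 CPM in the latter. HLA-DRB1 fell from 91.5 to 0.249 and 0.522 CPM and HLA-DPA1 from 70.5 to 1.26 and 0.518 CPM. HLA-DMA fell least, from 23.6 to 3.11 and 4.55 CPM, and RFX5, which binds the same promoters, was not called in either (adjusted p = 0.0788 and 0.337). Class II transcripts were also lower in 1GXLM controls than in MDA-MB-231 controls, where 8 of 12 fell. In SUM149PT at 1000 ng the median of the 12 genes was 0.871 above controls with 0 called (camera p = 4.56e-11; p = 0.0574 with an estimated correlation). CD74 and HLA-DRA are also members of the leukocyte list called at that dose, so the 2 results overlap. Reads shared among HLA copies leave the single values uncertain.

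The tumour suppressor CDKN2A, which is deleted in many tumours, had 0 counts in all 27 libraries, which at their total depth allows a level of up to 0.00117 CPM, and its neighbour CDKN2B had 1 count.

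In SUM149PT control replicate 1, 12 genes that are high in the PD-L1 shRNA group of 1GXLM and near 0 in the other SUM149PT libraries stood at a median of 2.95% of the level in that group (quartiles 2.78 to 3.2), and 9 genes chosen in the same way from 1GXLM controls at 3.23%. The NOTCH3 shRNA group gave 2.83% (12 genes). MDA-MB-231 controls gave 2.21% (5 genes, quartiles 1.83 to 3.09), so these shares alone do not settle which of the 2 lines was the source. Abundant MHC class II genes argue against control cells of either line at such shares. CD74 stood at 5.4 ± 1.7 CPM in SUM149PT controls and 5.58 ± 1.12 CPM at 500 ng. Controls of MDA-MB-231 and 1GXLM had 769 and 442 CPM. HLA-DPA1 was at 0.626 ± 0.321 and 0.741 ± 0.261 CPM, against 145 and 70.5 CPM. In the NOTCH3 shRNA and PD-L1 shRNA groups CD74 was at 0.859 and 4.53 CPM. Across genes, the log2 change in SUM149PT followed gene length with a Spearman correlation of -0.33 at 500 ng and -0.262 at 1000 ng over 13963 genes, against 0.0747 and 0.141 with AV535 in MDA-MB-231 and 1GXLM and 0.247 between the controls of those 2 lines.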
